A study of Nitrosomonas europaea ATCC 19718 with 9 samples.

How the data were processed

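Total RNA of the ammonia-oxidising bacterium Nitrosomonas europaea (strain ATCC 19718) was measured on 9 one-colour arrays. Per the labels' protocols, cells grew in the dark in a chemostat, a reactor with a steady flow of fresh medium, with a working volume of 3 L, a hydraulic retention time of 2.2 d, 25 °C, 2.0 mg/L dissolved oxygen and a pH of 7.45, on medium with 10 mM ammonium sulfate. Titanium dioxide (TiO2) nanoparticles were added to reactor and medium at 50 mg/L (50 ppm), and samples of 40 mL were taken before the addition and after 12 and 40 d. RNA was labelled with the dye Cy3 and hybridised to an Agilent array made for this genome, per the labels' protocols. The series' design text speaks of 3 independent experiments. The labels do not say which arrays came from which experiment or whether separate reactors were run, so p-values measure the spread between these samples.

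The authors deposited the scanner output of each array, and its values are spot intensities. Per the file headers and the submitters' processing notes, the images were read with Agilent Feature Extraction 11.0.1.1, which subtracted the background and removed spatial trends to give the processed signal. No normalization between arrays is recorded there. The authors also deposited 4 lists of genes changed at least 2-fold, higher and lower at day 12 and at day 40 against day 0. These lists give a linear fold change (a ratio) and group means of normalized log2 intensity, and each deposited p-value stands beside a false discovery rate. The raw group means beside them were not used. The test, its threshold and the normalization behind the lists are not given in the sources used here. The lists hold 461 entries, and 1 further line was emptied in the copy used here.

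Each array file holds 14616 spots of 2436 genes, with 1 probe per gene printed as 6 spots, and 536 control spots. Control spots and spots marked as outliers were left out, log2 of the processed signal was taken, the array's 75th percentile was subtracted, and the spots of a probe were averaged. A gene was kept where most of its spots were well above background on every array of at least 1 group. This kept 2364 genes and left out 72. No spot was saturated on any array. All fold changes are differences of these log2 values, and a value of 0 is the array's 75th percentile.

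Groups were taken from the sample titles, with 3 arrays at day 0, 3 at day 12 and 3 at day 40. All 9 arrays entered 1 linear model (limma 3.58.1 in R 4.3.3, with the package data.table at version 1.17.8), and each comparison was tested two-sided with moderated variances and 8.77 degrees of freedom. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Arrays of the same number deviated from their group means together between day 0 and day 12, with correlations over genes of 0.527, 0.654 and 0.164. The numbers were therefore taken to pair these groups, from the values alone, since the labels do not say what a number marks. Deviations cancel out within a group, so these correlations are not independent evidence. The third array did not correlate best with its own number. The model held no block, and a fit with the number as a block was an alternative. The precision is limited by the number of arrays per group. The median standard error of a log2 fold change was 0.227.

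Gene products and positions were taken from the authors' deposited lists, which name 384 genes, 382 of them tested. The files do not pair the other locus tags with a product. Of the 29 gene lists fixed before the data were examined, 27 had a member with a product and 20 had at least 4, the smallest size tested. Lists were tested with camera at a preset inter-gene correlation of 0.01. The plan was to test each list against all tested genes, but the named genes had been selected for change, so the other named genes were used as the background instead. The genes of these lists were therefore chosen by the authors on these same samples, and counts within a list are not independent evidence of its direction. The lists for ammonia monooxygenase, hydroxylamine oxidation and nitrogen oxide metabolism had also been fixed by locus tag, and those were tested over all genes, with adjustment over these 3 lists.

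The genes named were chosen by a rule fixed before the data were examined. It took, among called genes whose groups did not overlap, the 8 highest and 8 lowest changes with a product that is not hypothetical, and the 2 highest and 2 lowest of any product, at day 12 and at day 40. For day 40 against day 12 it took the 5 highest, the 5 lowest and 1 of any product on each side. It added the 2 members of each list with the lowest adjusted p and all measured genes of the ammonia monooxygenase and hydroxylamine oxidation lists. Other genes named as members of a list or of a run of loci were chosen after their values were seen. Transposases were not named one by one, because signal from near-identical copies cannot be assigned to 1 of them.

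The model was tested on simulated arrays with the measured means and spreads and no pairing, with 200 of the 2364 genes changed, in 20 runs. In the day 12 comparison it recovered a median of 20.9% of genes changed 1.5-fold, 58.2% of those changed 2-fold and 90.9% of those changed 4-fold, and 4.02% of its calls were false. In the day 40 comparison these shares were 21.6%, 56.7% and 91.7%, with 4.98% false. Each gene had the same spread on all simulated arrays, pooled over the groups. These shares therefore do not cover arrays of unequal spread, such as the third array of day 40 described below. The list test was checked on 20 simulated sets of arrays with 20 lists over 382 genes, in which each gene varied independently of the others. With no list shifted, it called a list in 1 of the 20 runs for day 12 and in 0 for day 40. With the tricarboxylic acid cycle list lowered by 1 log2 unit, it called that list in 20 of 20 runs in both comparisons. The check cannot show the error rate of the list test where genes vary together.

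Alternatives fixed beforehand were quantile and median normalization, normexp background correction with an offset of 50, other filters on dim probes, keeping outlier spots, fitting only the 2 groups compared, an intensity trend, array weights, the replicate number and the slide as blocks, a 2-fold minimum, an unmoderated test, leaving out each array, and other tests of the lists. Arrays with the same scan date in the file header were taken as sharing a slide. The normexp correction used the median signal of the spots, since the deposited columns do not include the mean. The medians of probes and the brightest probe were not run, since each gene has 1 probe. Leaving out the third arrays of groups, and leaving out the probes whose name begins with RNA_, were alternatives added after the data had been seen.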

Results

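Expression of the genome of Nitrosomonas europaea, a bacterium that lives by oxidising ammonia to nitrite, was measured in a continuous culture before and during exposure to TiO2 nanoparticles at 50 ppm. Samples fell into 3 groups of 3 arrays, taken before the nanoparticles were added (day 0), after 12 d of exposure (day 12) and after 40 d (day 40). The series compares both exposure times with day 0, as a study of chronic nanoparticle stress. The titles tag day 12 as exp and day 40 as rec. The labels describe both as exposed to 50 ppm, which is followed here, and the sources used here do not explain the tag rec. No unexposed culture of day 12 or day 40 was analysed here, so exposure and time in culture cannot be told apart. Values are log2 signal relative to the array's 75th percentile, and a call is an adjusted p under 0.05 in limma.

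The 75th percentile of the signal ran from 1640 to 2345 on 8 arrays, and 2305 to 2386 of the 2436 genes were well above background on them. The third array of day 40 was dimmer, with a 75th percentile of 775.3, 2124 genes well above background and 491 outlier spots, against 134 to 181 on the others. By scan date, it was the only array of slide 2, and the other 8 shared slide 1. Across genes, which are not independent replicates, it correlated with the other day 40 arrays at a mean r of 0.914, and those correlated with each other at 0.987. The third arrays of day 0 and day 12 lay between the first and second arrays of their group. Of the genes at least 2-fold apart between the first and second arrays, 100% of 183 at day 0 and 99% of 96 at day 12 lay between them on the third array. In both groups the third array lay closer to a linear mixture of the first and second than to an interpolation on the log scale, with median distances of 0.0441 against 0.111 at day 0 and 0.0724 against 0.183 at day 12. In simulated arrays in which the third arrays of day 0 and day 12 were such mixtures, 43.3% of the calls at day 12 and 33.3% of those at day 40 were false. The total called in each comparison, and the total called at both times in the same direction, are therefore given also without these arrays. The simulated shares were obtained with 200 of the 2364 genes changed, and were 4.02% and 4.98% without mixing. They show that such mixtures can raise the share of false calls. They do not estimate that share among the calls made here, since the number of genes truly changed is not known. Other counts of genes, such as those within a list, of 2-fold changes, of opposite directions and of runs of loci, are from all 9 arrays. For the lists, how many of those calls were kept without the third arrays is given over all lists of a comparison.

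**Figure D1:**
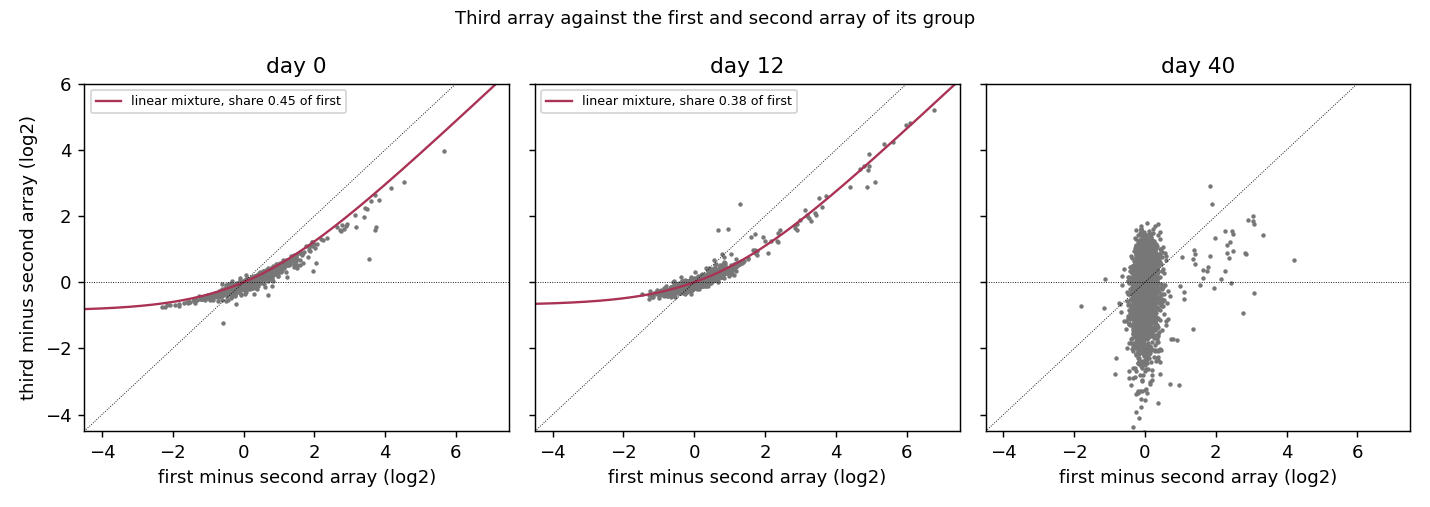
Each point is 1 gene, with the first minus the second array of a group on the x axis and the third minus the second array on the y axis, both in log2 units, and the line is the best linear mixture of the first and second arrays. At day 0 (share 0.45 of the first array) and day 12 (share 0.38) the third array follows that line, and at day 40 it spreads widely while the first and second arrays lie close together.

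After 12 d, the genes of an efflux system and of a sensor kinase and response regulator beside it were far above their day 0 level. NE0670, a membrane fusion protein (MtrC) of the kind that links an inner-membrane pump to the outer membrane, rose by 5.59 ± 0.43 (log2, SE, n = 3 per group), or 48.2-fold, from -5.52 ± 1.02 to 0.07 ± 0.12 (SD), with an adjusted p of 0.000279 in limma. It was well above background on 1 of the 3 day 0 arrays, and with the other 2 raised to the lowest signal of a gene well above background it was 40.2-fold higher. NE0669, an acriflavin resistance protein (an inner-membrane pump), rose by 4.36 ± 0.23, and the sensor histidine kinase NE0666 and the response regulator NE0667 rose by 3.70 ± 0.31 and 2.78 ± 0.19. The largest measured decrease was that of NE0583, listed as hypothetical (-3.40 ± 0.36). Among genes whose product is not hypothetical, the periplasmic sulfate-binding protein NE0582 (sbp1) fell most, by 3.10 ± 0.47, and NE1240, listed as a cyclooxygenase, fell by 2.90 ± 0.37.

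NE0666 to NE0670 lie next to each other, from 721379 to 728997 on the chromosome in the authors' coordinates, whose genome build is not given in the sources used here. The outer membrane efflux protein of the same stretch, NE0668, rose by 1.12 ± 0.17. NE1498 and NE0547 were also well above background on only 1 of the 3 day 0 arrays, so their day 0 means rest mostly on weak signal. A run of 11 consecutive loci that ends with NE0583 fell, with a median of -1.70, and so did a run of 16 from NE1230 to NE1245, with a median of -1.92. The first holds the sulfate transport genes cysU (NE0578, -2.04 ± 0.30), cysA and cysW, and the second holds mostly genes listed as hypothetical, with NE1237, a glucose-methanol-choline oxidoreductase (-2.35 ± 0.19), the peroxidase NE1233 (-1.92 ± 0.31) and the tyrosinase NE1241 (-2.46 ± 0.47).

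Genes of nitrogen metabolism moved in both directions at day 12. In the nitrogen oxide list all 4 members with a product rose, by a mean of 1.74. They were NE0924 (aniA, listed as a multicopper oxidase and named after a copper nitrite reductase, 2.27 ± 0.39), the cytochrome c NE0926 (1.99), the multicopper oxidase NE0927 (pan1, 1.26) and NE1919 (1.42 ± 0.20). NE1919 is listed as the nitric oxide reductase protein NorQ but carries the symbol cbbQ, a carbon fixation gene. The other 3 lie in a run of neighbouring loci, NE0924 to NE0927. Camera gave an adjusted p of 0.124, and over the 10 loci fixed by tag, 4 rose, 1 fell and the adjusted p was 0.505. NE0448 (Rh50), an ammonium transporter, fell by 2.42 ± 0.38. The files give no product for the loci fixed for ammonia monooxygenase, the enzyme that oxidises ammonia. Of these, 5 were measured, and NE0943 (-1.07 ± 0.33) and NE1411 (-0.84 ± 0.19) fell, with 4 lower when adjusted over the list alone. The median was -0.79 and camera over all genes gave an adjusted p of 0.0205, or an adjusted p = 0.249 with an estimated correlation. That call was also lost without the second day 0 array (0.0553) and with quantile normalization of the processed signal (0.115) or of the normexp values (0.117). The mean of the list relative to the other genes was -0.90, against -0.70, -0.76 and -0.74 in those 3 fits. This genome carries near-identical copies of these genes, so the loci are not independent measurements. Of 6 measured loci fixed for hydroxylamine oxidation, the next step, 0 were called by limma (0 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p 0.488), with log2 fold changes from -0.43 to 0.13.

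In the list of translation factors and tRNA synthetases 6 of 7 members rose at day 12 and 1 was not past the threshold, with cysS (NE0043, cysteinyl-tRNA synthetase) up by 1.15 ± 0.13. NE0857, listed as a GTP-binding elongation factor, carries the symbol cysN of a sulfate enzyme and rose by 1.46 ± 0.14. The gene greB, a transcription factor caught by the list, had -0.97. Adjusted over the list alone, 7 changed, greB downward. Ribosomal proteins rose in 4 of 7 cases (6 adjusted over the list alone), among them rpsB (NE1718, 1.16 ± 0.18), and a member not past the threshold, rimO, modifies ribosomal protein S12. In the amino acid list 14 members rose and 4 fell. Of its histidine synthesis genes, hisC1 (NE0647) rose by 2.57 ± 0.42, hisF by 1.76, hisA by 1.17 and hisZ by 1.11. The 4 that fell were the transporter genes cysA, cysW and cysU and the sulfate reduction gene cysH. Among those that rose, purK (NE0867) serves purine synthesis and glyQ translation. Symbol and product leave open whether NE0857 serves translation or sulfate use. All 5 members of the tricarboxylic acid cycle list fell, among them sdhD (NE1047, a succinate dehydrogenase subunit, -1.43 ± 0.30) and sucB (NE2375, -1.22 ± 0.20). Camera gave an adjusted p of 0.122 for each of these 4 lists and of 0.272 with an estimated correlation. Differences between the lists were not tested, and these counts rest on genes that the authors had selected on the same samples.

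Of the 382 tested genes with a product, 162 rose and 117 fell at day 12 (42.4% and 30.6%). At day 40 34.3% rose and 26.4% fell, and between day 12 and day 40 16.8% rose and 17.3% fell. The counts within lists are to be read against these. In the list of sigma factors, which direct RNA polymerase to promoters, 4 of 5 members rose, such as NE1041 (1.09 ± 0.15) and NE0547 (1.06 ± 0.22). In signalling 5 of 7 rose, including pilG (NE1836, 1.22 ± 0.17). All 3 members of the carbon fixation list rose, NE1919 again among them and tpiA (NE1779, triosephosphate isomerase) by 1.57 ± 0.21, and both TonB-dependent receptors, which import iron complexes, rose (NE0636, 1.57 ± 0.17; NE0731, 1.13 ± 0.20). In cofactor and haem synthesis 5 of 9 rose and 1 fell, with coproporphyrinogen oxidase (NE0278) at 1.43 ± 0.24 and hemE (NE0445) at 1.14 ± 0.19. In the metal resistance and efflux list 4 of 8 rose and 2 fell, which also caught the multicopper oxidases aniA and pan1, with the outer membrane efflux protein NE0373 at 1.39 ± 0.14 and merD (NE0838, a regulator of mercury resistance) at -1.44 ± 0.17. Transposases and phage genes fell in 5 of 6 cases, and in the list meant for DNA replication 4 of 8 members fell and 2 rose. Those that fell include the restriction enzyme subunits hsdR (NE0382, -2.22 ± 0.45) and NE2527 (-2.07 ± 0.40). Chaperones and proteases fell in 2 of 6 cases, htpX (NE1421, a membrane protease, -0.99 ± 0.14) and ftsH (NE0906, -1.04 ± 0.25). In the wall and division list 5 of 9 fell and 2 rose, with ftsQ (NE0995) at -0.84 ± 0.20, and in the outer membrane list 6 of 12 rose and 3 fell. In the list of secretion and pili, which also holds pilG, 4 of 6 rose and 1 fell, with tatC (NE0637, of the twin-arginine exporter) at 1.38 ± 0.27. In the DNA repair and recombination list 3 of 4 members fell, 2 of them site-specific recombinases named tnpR, and of the respiratory chain list 1 of 7 rose and 1 fell. Oxidative stress genes split, with 2 of 6 higher and 2 lower, and the list of other membrane transporters, which shares NE1117 with the efflux list, likewise, with 6 of 16 higher and 6 lower. Camera called 0 of 20 lists at day 12, where fry, which asks only whether members move one way, called 15. The lowest unadjusted camera p was 0.0116, for transposases and phage genes, and 8 lists had one under 0.05.

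In all, 579 of 2364 genes were called at day 12 (24.5%), 332 higher and 247 lower, and 255 of them changed at least 2-fold. The groups did not overlap for 1300 genes (55%). Chance gives 10% for 3 independent arrays per group, and more where the third array lies between the first and second, as in both groups here. Without the third arrays of day 0 and day 12, 7 genes were called, all among the 579. They were NE0666, NE0667, NE0669, NE0670, NE1237, a locus listed as hypothetical and a locus without a product here. Leaving out the third arrays of all groups as well, 378 were called, 310 of them among the 579, and 645 when the replicate number was a block as well. Of the 59 called results named by rule in this comparison, 5, 52 and 59 were called in these fits. Of the 110 calls among members of the lists, 2, 76 and 99 were kept. With the slide as a block, or within slide 1, 1135 were called, which is also the count without the third array of day 40. Leaving out other arrays gave 340 (the second of day 0), 242 (the third of day 0), 381 (the first of day 12), 348 (the second of day 12) and 240 (the third of day 12). Each remaining array left out alone gave 526 to 576. A fit of the day 0 and day 12 arrays alone called 1005, array weights 2225, and an unmoderated test with a 2-fold minimum 282 before and 249 after adjustment.

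**Figure D2:**
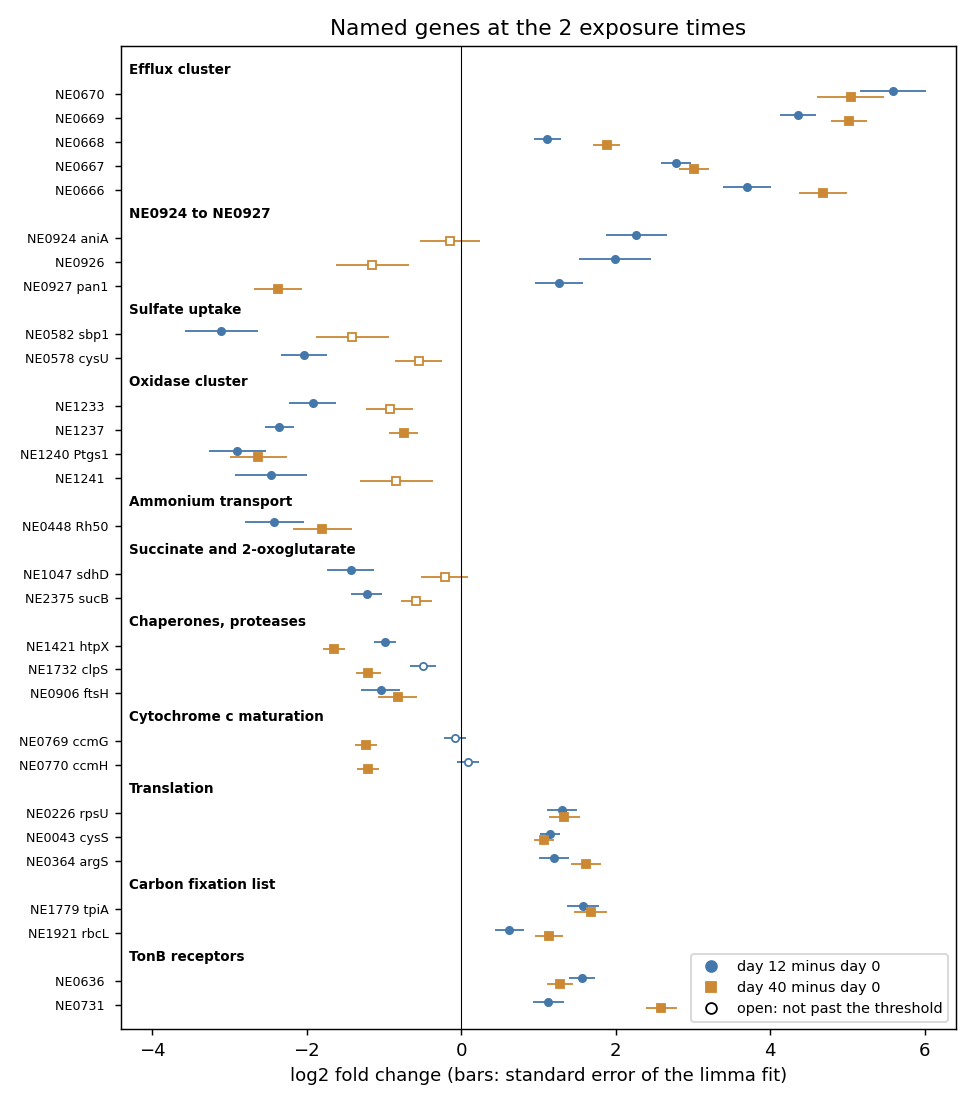
Points give the log2 fold change against day 0 (x axis) of named genes, at day 12 (circles) and day 40 (squares), with bars for the standard error of the limma fit and open symbols where the adjusted p was 0.05 or more. NE0670, NE0669 and NE0666 lie furthest to the right at both times, and the sulfate uptake genes lie further left at day 12 than at day 40.

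After 40 d, the efflux genes NE0670 and NE0669 and the kinase NE0666 had the largest increases among genes well above background on at least 1 day 0 array. NE0670 rose by 5.04 ± 0.43, NE0669 by 5.02 ± 0.23 (32.4-fold, adjusted p 1.52e-05 in limma), NE0666 by 4.68 ± 0.31, NE0667 by 3.02 ± 0.19 and NE0668 by 1.88 ± 0.17. NE0231, listed as hypothetical, was at least 9.79-fold higher by the bound explained below for NE1101, and was well above background on 0 of 3 day 0 arrays and on 3 of 3 day 40 arrays. The TonB-dependent receptor NE0731 rose by 2.59 ± 0.20, CTP synthetase (NE1045, pyrG) by 2.30 ± 0.19, the cold shock protein gene cspD2 (NE1312) by 2.15 ± 0.21 and the RNA helicase NE1807 by 2.05 ± 0.16. NE2508, listed as hypothetical, had the largest measured decrease (-3.55 ± 0.34). Among genes whose product is not hypothetical, NE1240 was lowest at -2.63 ± 0.37, followed by the multicopper oxidase NE0927 (-2.37 ± 0.31), flagellin (NE1593, hag, -1.93 ± 0.44), the protease mucD (NE2329, -1.83 ± 0.39) and the ammonium transporter Rh50 (NE0448, -1.80 ± 0.38).

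All 6 members of the list of chaperones and proteases fell at day 40 (6 adjusted over the list alone), with a median of -1.38, among them htpX (NE1421, -1.65 ± 0.14), clpS (NE1732, an adaptor of the Clp protease, -1.20 ± 0.17) and the chaperone genes dnaK and grpE. Camera called this list at an adjusted p of 0.0311, with an adjusted p = 0.62 with an estimated correlation. The call was lost with the slide as a block or without the third array of day 40 (adjusted p 0.0618) and without the third arrays of all groups (0.0541), and was kept when the replicate number was a block as well (0.0452). The mean of the list relative to the other named genes was -1.44, against -1.31 with the slide as a block or without the third array of day 40 and -1.30 without the third arrays of all groups. The authors had selected its members on these samples.

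The cell envelope lists were mixed. In the peptidoglycan and division list 7 of 9 fell and 1 rose, mreB (NE2070, which sets rod shape) by 1.67 ± 0.18. The 7 included the wall synthesis genes mraY, murB, murC, murD and murG and the division gene ftsQ (NE0995, -1.38 ± 0.20), which lie in a run of 8 loci, NE0988 to NE0995, that all fell (median -1.15). In the outer membrane and lipopolysaccharide list 4 of 12 rose and 5 fell, with the lipoprotein NE2391 at -1.20 ± 0.15. Another run of 6 loci up to NE0772 also fell (median -1.22) and holds the cytochrome c maturation genes ccmG (NE0769, -1.23 ± 0.14) and ccmH (NE0770, -1.21 ± 0.14) and the peroxiredoxin gene bcp (NE0772, -1.50 ± 0.24). Camera gave adjusted p of 0.116 and 0.897 for the envelope lists.

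In the ribosomal protein list 6 of 7 members rose at day 40, rimO among them (rpsU, 1.34 ± 0.20; NE1671 rpsP, 1.07 ± 0.15), and of translation factors and tRNA synthetases 4 of 7 rose (NE0364 argS, 1.62 ± 0.20; NE1187 glyQ, 1.61 ± 0.21). Camera gave adjusted p of 0.113 and 0.215. In the amino acid list 6 of 18 rose and 0 fell (7 higher and 0 lower adjusted over the list alone), though 3 of the 6 were NE0857, purK and glyQ, with aroB (NE1981, of aromatic amino acid synthesis) at 1.14 ± 0.15 and an adjusted p of 0.269. In the carbon fixation list 3 of 3 were called higher, 1 of them NE1919, whose call was lost with the replicate number as a block (adjusted p 0.0584) and in 2 of the 3 fits that leave out the third arrays, with rbcL (NE1921, the large subunit of the carbon dioxide fixing enzyme) at 1.14 ± 0.19 and tpiA at 1.68 ± 0.21. In the respiratory chain list 2 of 7 rose and 2 fell, with coxB (NE0684, a cytochrome oxidase subunit) at 1.25 ± 0.20 and nuoJ (NE1768, an NADH dehydrogenase subunit) at -1.42 ± 0.21. Of the tricarboxylic acid cycle list 0 of 5 were past the threshold in limma (1 at an unadjusted p under 0.05), with log2 fold changes from -0.58 to 0.08, camera gave an adjusted p of 0.52, and fry gave 0.0366, downward. In the nitrogen oxide list NE1919 had 0.63 (adjusted p 0.0492, lost with that block), NE0927 fell, and aniA (-0.15 ± 0.39) and NE0926 (-1.15) were not past the threshold. Of the loci fixed for ammonia monooxygenase 1 of 5 fell (NE1411, -1.78 ± 0.19), and camera gave an adjusted p of 0.639.

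In oxidative stress defence 2 of 6 rose and 2 fell, with grxC (NE2211, glutaredoxin) at 1.18 ± 0.15 and bcp lower. Signalling genes rose in 5 of 7 cases, and members of the sigma factor list in 3 of 5, where NE0061 is listed as a sigma-54 modulation or ribosomal protein. The sigma factor NE1101 was not well above background on any day 0 array and was so on 2 of the 3 day 40 arrays. It was at least 1.42-fold higher at day 40 (adjusted p 0.0187 in limma), taking for each day 0 array the higher of the gene's own signal and the lowest signal of a gene well above background. The metal resistance and efflux list does not hold NE0669 or NE0670. Of its 8 members 1 rose (NE0668) and 3 fell, the copper transporter copA, the multicopper oxidase pan1 and the outer membrane efflux protein oprN. Of the transporter list 5 of 16 rose and 1 fell, with the major facilitator transporter NE2454 at 1.94 ± 0.20. Transposases and phage genes fell in 3 of 6 cases. Cofactor and haem synthesis had 2 of 9 higher and 4 lower, and the secretion and pili list 3 of 6 higher and 1 lower. Camera called 1 of 20 lists at day 40 and fry 14.

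At day 40, 535 genes were called (22.6%), 279 higher and 256 lower, 221 of them at least 2-fold. Which side was larger turned with the scaling, with 253 higher and 299 lower when the median of each array was subtracted. Groups did not overlap for 971 genes (41.1%). For 3 independent arrays per group chance gives 10%, and it gives more with the third day 0 array between the first and second. Without the third arrays of day 0 and day 12, 32 were called, all among the 535, including NE0666 to NE0670, NE0731, pyrG, cspD2, NE1807, mreB, htpX and NE0927. With the third arrays of all groups left out, 186 were called, 164 of them among the 535, and 441 with the replicate block as well. Of the 54 called results named by rule, 17, 44 and 53 were called in these fits. Of the 88 calls among members of the lists, 11, 49 and 80 were kept, and of the 6 among chaperones and proteases 1, 3 and 5. With the slide as a block, within slide 1, or without the third array of day 40, 876 were called. Other arrays left out gave 302 (the second of day 0), 197 (the third of day 0) and 331 (the third of day 12), and each remaining array left out alone gave 371 to 507. A fit of the day 0 and day 40 arrays alone called 243, array weights 1781, and the unmoderated test with a 2-fold minimum 199 before and 73 after adjustment.

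**Figure D3:**
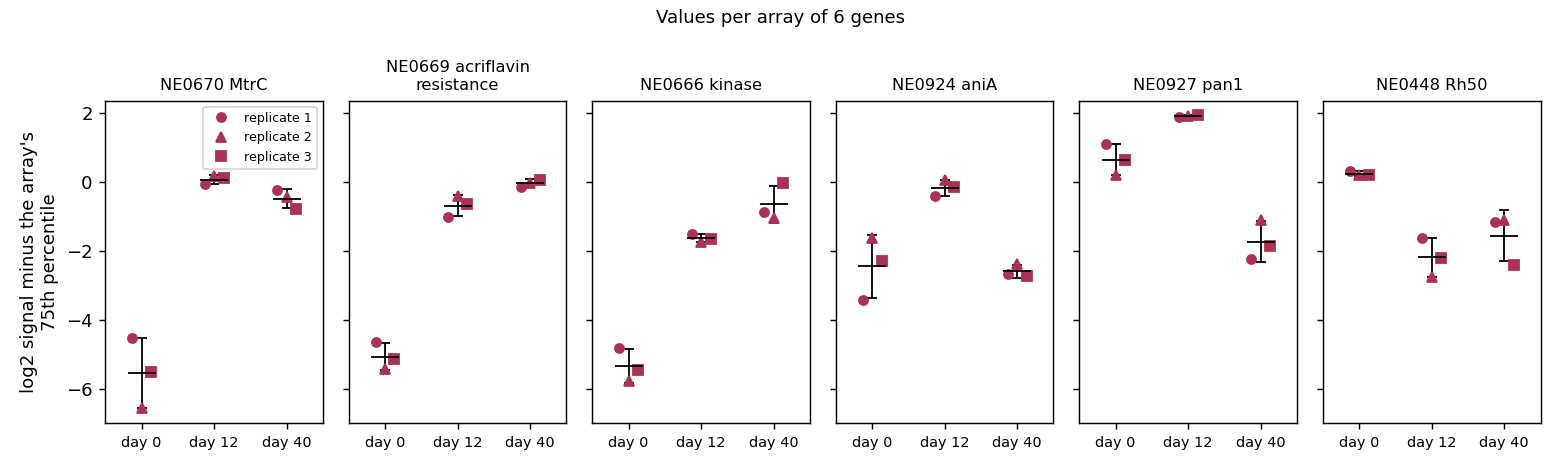
Each panel shows 1 gene, with the log2 signal minus the array's 75th percentile of each array on the y axis and the day on the x axis, and bars for the mean and SD of 3 arrays. NE0670, NE0669 and NE0666 lie higher at day 12 and day 40 than on any day 0 array, aniA and pan1 (NE0927) are highest at day 12, and Rh50 (NE0448) is highest at day 0.

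Day 40 against day 12 shows which levels differed between the exposure times. The run NE0924 to NE0927 was higher at day 12 than at day 40 in all 4 loci. NE0927 fell by 3.64 ± 0.31 (12.4-fold, adjusted p 0.00134 in limma), from 1.91 ± 0.02 to -1.73 ± 0.585 (SD, n = 3), NE0926 by 3.14 ± 0.47 and aniA (NE0924) by 2.42 ± 0.39. The biotin synthase gene bioB (NE2300) fell by 1.93 ± 0.20, as did pyrE (NE1734, of pyrimidine synthesis, -2.20 ± 0.48). The cyanophycin synthetase gene cphA (NE0922), for a nitrogen storage polymer, rose by 2.52 ± 0.27, and phoB (NE2131), the response regulator of phosphate starvation, by 1.57 ± 0.34. The sulfate-binding protein NE0582 (1.69 ± 0.47) and the oxidoreductase NE1237 (1.61 ± 0.19) were higher at day 40 than at day 12, though NE0582 was not called with the replicate number as a block (adjusted p 0.0508). NE0582 and phoB were called in none of the 3 fits that leave out the third arrays. The LysM domain protein NE2076 rose by 1.76 ± 0.43.

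The nitrogen oxide list fell in all 4 members with a product, by a median of -2.78, and cofactor and haem synthesis in 4 of 9, by a median of -0.96. Camera called both at an adjusted p of 0.0175, with an adjusted p = 0.303 with an estimated correlation for each. Over the 10 loci fixed by tag for nitrogen oxides, 4 fell and the adjusted p was 0.135. Of the nitrogen oxide list's 4 members with a product, 3 lie in the run NE0924 to NE0927. Without NE1919, the remaining member, that list would be too small to test. The tricarboxylic acid cycle list had 2 of 5 higher (4 adjusted over the list alone, adjusted p 0.0932), and the amino acid list 4 of 18 higher, which were cysA, cysW, cysU and glyQ, and 6 lower (adjusted p 0.562). Chaperones and proteases were lower in 3 of 6 cases (adjusted p 0.181).

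In this comparison 351 genes were called (14.8%), 149 higher and 202 lower, 169 of them at least 2-fold. The excess of lower genes was absent with quantile normalization (206 higher and 206 lower). Groups did not overlap for 1011 genes (42.8%). For 3 independent arrays per group chance gives 10%, and it gives more with the third day 12 array between the first and second. Without the third arrays of day 0 and day 12, 2 were called, NE0927 and a locus listed as hypothetical (NE0231). Once the third arrays of all groups were left out, 45 were called, 40 of them among the 351, and 193 with the replicate block as well. Of the 11 called results named by rule 2, 5 and 9 were called in these fits. Of the 46 calls among members of the lists, 1, 5 and 23 were kept. With the slide as a block, within slide 1, or without the third array of day 40, 669 were called. Other arrays left out gave 174 (the third of day 0), 162 (the first of day 12), 146 (the second of day 12) and 80 (the third of day 12). Each remaining array left out alone gave 237 to 387. A fit of the day 12 and day 40 arrays alone called 213, array weights 1677, and the unmoderated test with a 2-fold minimum 177 before and 63 after adjustment.

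Changes at the exposure times overlapped. Among genes called against day 0 at both times, 146 were higher at both, 105 lower at both and 14 moved in opposite directions, against 39.2, 26.7 and 65.1 for independent lists of these sizes. The comparisons share their day 0 arrays. In 50 simulations of unchanged groups against shared controls 0 genes were called at both times, but unchanged groups give few calls, so this does not measure the overlap that shared controls give among changed genes. The fold changes correlated at r = 0.61 across genes, against 0.495 with no effect, and their covariance was 0.298 against 0.06, a difference of 0.238. The 3 day 0 arrays could not be split into parts of at least 2, so part of the excess may come from the shared controls. Genes of opposite direction with a product were pan1 (NE0927), cphA (NE0922), bioF (NE2299) and the biotin synthase gene bioB (NE2300). The count called at both times in the same direction, 251, was 4 without the third arrays of day 0 and day 12, 97 without the third arrays of all groups and 231 with the replicate block as well. It was 550 with the slide as a block or without the third array of day 40. Other arrays left out gave 134 (the second of day 0), 83 (the third of day 0), 152 (the second of day 12) and 106 (the third of day 12). Each remaining array left out alone gave 175 to 240.

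**Figure D4:**
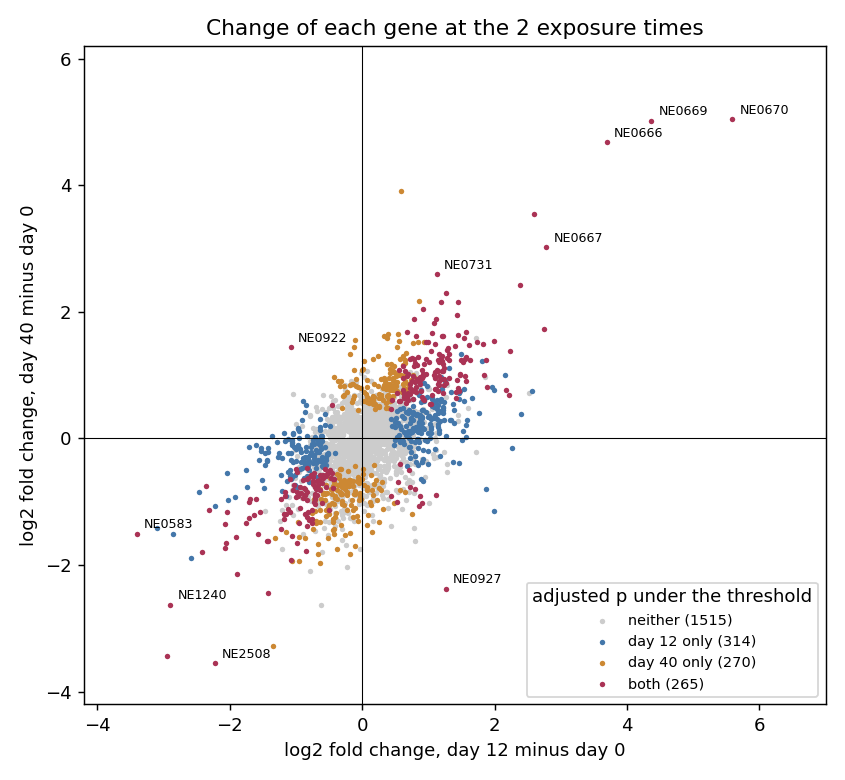
Each point is 1 of 2364 genes, with its log2 fold change at day 12 against day 0 on the x axis and at day 40 against day 0 on the y axis, coloured by where the adjusted p was under 0.05. NE0666, NE0667, NE0669 and NE0670 lie at the upper right, and NE0927 is higher at day 12 and lower at day 40.

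The authors' deposited tables list 143 genes higher and 125 lower at day 12, and 109 higher and 84 lower at day 40. All 267 listed genes tested here for day 12 and all 192 for day 40 had the same direction as in the authors' deposited tables, and 236 (88.4%) and 187 (97.4%) were called here. Those tables rest on these same samples and hold only genes changed at least 2-fold, so the shared direction is no independent evidence. The authors' deposited tables give a fold of 48.3 for NE0670 at day 12 and 32.6 at day 40. Their false discovery rates reach 0.103 at day 12 and 0.183 at day 40, and values above 0.05 belong to 10 higher and 19 lower genes at day 12 and to 56 and 51 at day 40.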

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

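The test of day 40 against day 12 was planned as a comparison, and the tests of the third arrays and of splits by pairs were chosen after the result was seen. In that comparison 351 genes differed, and 32 of the 86 genes named in the comparisons with day 0 were among them. Their effects against day 0 at day 12 and day 40 therefore differed by the limma test, and the values below are log2, day 40 minus day 12, n = 3 per group.

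Genes lower at day 40 than at day 12 included pan1 (NE0927, -3.64), aniA (NE0924, -2.42), hisC1 (NE0647, -1.81), mucD (NE2329, -1.65), nusG (NE2051, -1.58), NE2508, listed as hypothetical (-1.33), and NE1919 (-0.79). The cytochrome c maturation genes ccmG (NE0769, -1.15) and ccmH (NE0770, -1.29) and the neighbouring bcp (NE0772, -1.31) fell between the exposure times. So did tatC (NE0637, -1.13), nuoJ (NE1768, -0.99), hemE (NE0445, -0.96) and the outer membrane efflux protein NE0373 (-0.94). NE0857, listed as an elongation factor (-0.71), clpS (NE1732, -0.70) and htpX (NE1421, -0.66) fell too.

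Genes higher at day 40 than at day 12 included NE0583 (1.90), listed as hypothetical, sbp1 (NE0582, 1.69, adjusted p 0.0508 with the replicate number as a block), cysU (NE0578, 1.49), NE1237 (1.61) and sdhD (NE1047, 1.21). The TonB-dependent receptor NE0731 (1.46), the RNA helicase NE1807 (1.13), exbB2 (NE1171, 1.105), merD (NE0838, 1.09), pyrG (NE1045, 1.03), mreB (NE2070, 1.00) and cspD2 (NE1312, 0.97) were also higher. Smaller differences were those of glyQ (NE1187, 0.81), grxC (NE2211, 0.80) and the outer membrane efflux protein NE0668 (0.76). Among the lists, nitrogen oxide metabolism (median -2.78) and cofactor and haem synthesis (median -0.964) were called by camera, but with an estimated correlation each had an adjusted p = 0.303. The 10 loci fixed by tag for nitrogen oxides had an adjusted p of 0.135. The call for nitrogen oxides rests mostly on the run NE0924 to NE0927, which holds 3 of the list's 4 members with a product.

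Only NE0927 among these 32 genes was called in this comparison without the third arrays of day 0 and day 12, where 2 genes of all 2364 were called. Leaving out single arrays gave 174 (the third of day 0), 162 (the first of day 12), 146 (the second of day 12), 80 (the third of day 12) and 669 (the third of day 40). Each remaining array left out alone gave 237 to 387.

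Regrouping the 6 arrays of a comparison gave too few splits for a share under 0.05. For day 12 against day 0, 1 of 10 splits gave as many called genes, the real one, with 579 against 0 in the highest other split. For day 40 against day 0 it was 1 of 10, with 535 against 0, and for day 40 against day 12 it was 1 of 10, with 351 against 0. For day 12 and day 0, whose arrays were taken as paired by number, 3 other splits also part all 3 pairs. They called 0 genes with the number as a block, where the real split called 609, and at most 11 genes had an unadjusted p under 0.05, against 922. With only these 3 and the real split, a share under 0.05 was again out of reach. The 6 splits that part 1 pair called 0, with at most 187 at that p. Without the block, at an unadjusted p under 0.05 the real splits gave 892, 878 and 772 genes and the highest others 159, 327 and 195. In every other split, a difference between the 2 groups adds to the spread within the regrouped arrays and lowers the number of calls. The low counts there are therefore no measure of chance.

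The third arrays of day 0 and day 12 lay between the first and second arrays. A mixture of the material of the first and second arrays may account for this. The distance from a linear mixture was at most 0.398 of the distance from a log interpolation in either group. That the third array was an independent culture was left open by the test, with a chance of 0.0182 for spreads this small in both groups if cultures varied along 1 shared axis. That chance is the product of 0.11 at day 0 and 0.165 at day 12. It takes the groups as independent, though their arrays were taken as paired by number, so it may be too small. If the third arrays were mixtures, the spread within day 0 and day 12 was understated, which by itself makes adjusted p values too small. The third day 40 array widened the shared spread, and without it 1135, 876 and 669 genes were called. The net effect on the adjusted p values of the 3 comparisons is therefore not settled.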

How the results depend on the processing

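The alternatives that leave out the third arrays of groups or the RNA_ probes were chosen after the result was seen, and the others before the data were examined. Of 150 results named by rule 124 were called, 83 kept the same reading under every alternative fixed beforehand other than leaving out an array, and 0 of the called ones reversed under any alternative run.

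Counts of called genes are given for day 12 against day 0, day 40 against day 0, day 40 against day 12, and both times in the same direction, where the unaltered counts were 579, 535, 351 and 251. Quantile, median and normexp scaling, other filters, kept outlier spots and an intensity trend moved none of these by over 1.5 times. The split by direction did move. At day 40 it was 279 higher and 256 lower, against 253 and 299 with median scaling and 293 and 202 with normexp and the 75th percentile. For day 40 against day 12 it was 149 and 202, against 206 and 206 with quantile normalization and 182 and 205 with normexp and quantile normalization. Array weights gave 2225, 1781, 1677 and 1355, with a weight of 591 on the third day 0 array and 0.0204 on the third day 40 array. The slide as a block, which is the same as leaving out the third day 40 array, gave 1135, 876, 669 and 550. Fitting only the 2 groups compared gave 1005, 243 and 213. A 2-fold minimum gave 255, 221, 169 and 85. An unmoderated test with a 2-fold minimum gave 282, 199, 177 and 77 unadjusted, and 249, 73, 63 and 34 adjusted. Leaving out 1 array gave 240 to 1135, 197 to 876, 80 to 669 and 83 to 550. Without the third arrays of day 0 and day 12 the counts were 7, 32, 2 and 4, without the third arrays of all groups 378, 186, 45 and 97, and with the replicate number as a block as well 645, 441, 193 and 231. The replicate number as a block gave 609, 534, 372 and 255, and changed no call of a named gene or list at day 12 against day 0. With it NE1919 at day 40 (adjusted p 0.0584) and NE0582 in day 40 against day 12 (0.0508) were no longer called. The cause of these differences was not tested.

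Lists called at day 40 against day 0 numbered 1, and 2 when genes had to be well above background on all 9 arrays. They numbered 0 with the slide as a block, 0 without the third arrays of all groups, 0 to 1 when single arrays were left out, and 0 with an estimated correlation. For day 40 against day 12 they numbered 2, and 0 with an estimated correlation. Fry called 15, 14 and 11 lists in the 3 comparisons.

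The genes whose estimate reversed were not called. NusG (NE2051) at day 12 had -0.037 with quantile normalization and -0.0023 with normexp and quantile normalization. At day 40, NE0943 had 0.25 with quantile normalization, 0.29 with normexp and quantile normalization, 0.14 with array weights, 0.23 with the slide as a block and 0.25 without the third arrays of all groups, with or without the replicate block. Array weights gave -0.0096 for NE2064, 0.058 for NE0960 and 0.069 for NE2042 at day 40, and 0.00028 for NE0962 at day 12. The slide as a block gave 0.039 for NE0960 and 0.023 for NE2042, and leaving out the third arrays of all groups gave 0.030 for NE0960, with or without the replicate block. Leaving out 1 array gave -0.38 to 0.23 for NE0943, -0.25 to 0.44 for NE0944, -1.05 to 0.039 for NE0960 and -0.94 to 0.023 for NE2042 at day 40. At day 12 it gave -0.56 to 0.18 for NE0962 and -0.060 to 0.36 for NE0961.

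Normexp scaling by the 75th percentile moved the median of all genes at day 40 to 0.112, from -0.0341. Deviations from the group mean correlated between arrays of the same number at 0.301, 0.325 and 0.0941 (day 0 with day 40) and 0.314, 0.42 and -0.111 (day 12 with day 40). One correlation in each was under 0.1, so the numbers were not taken as pairs in the comparisons with day 40. Every array correlated best with its own number except the third in the comparisons that include day 12. Fits without an array kept the gene set of all arrays. The lists were not rerun under the intensity trend, array weights, the 2-fold minimum or the unmoderated test, and the median or brightest of a gene's probes was not run, since each gene has 1 probe.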

Other observations

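The tests of the RNA_ probes, of the third day 40 array and of runs of loci were chosen after the result was seen. Single genes outside the fixed lists were also called. The rule had named apt at day 12 and cphA in day 40 against day 12. The others were picked after their values were seen, so they stand for no group. At day 12 the tRNA modification genes trmB, truB and queA rose by 1.95 ± 0.34, 1.42 ± 0.18 and 1.16 ± 0.25 (log2, SE), while the tRNA modification gene trmE was not past the threshold (0.94, adjusted p 0.125). The gene gatA, which corrects mischarged tRNA, rose by 1.99 ± 0.25 at day 12 and by 1.54 ± 0.25 at day 40. The purine salvage gene apt rose by 2.75 ± 0.36 and 1.73 ± 0.36 at the exposure times, adenylosuccinate lyase (NE1951) by 1.54 ± 0.24 and 1.59 ± 0.24, and adenylate kinase (adk) by 1.65 ± 0.24 at day 40. SCO1 (NE0509), a copper chaperone of cytochrome oxidase, rose by 2.17 ± 0.22 at day 12.

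The restriction genes mcrC and hsdM (NE0385) fell at day 12, with -2.02 ± 0.32 and -0.97 ± 0.21. At day 40 the protease gene lonA (NE1278) and the small heat shock protein NE2074 fell, with -1.34 ± 0.27 and -1.24 ± 0.17. Not all such genes outside the list fell at day 40, with the serine protease NE1508 higher (0.73, adjusted p 0.0327) and NE1183 (-0.43, adjusted p 0.406) and the protease factor gene sspB (0.45, adjusted p 0.117) not past the threshold. The genes glgC and amyA had -1.57 ± 0.43 and -1.12 ± 0.30 at day 40, while NE0190, listed as an ADP-glucose pyrophosphorylase, had 0.75 (adjusted p 0.0629) and cphA (NE0922) rose by 1.44.

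Runs of at least 4 consecutive loci called in 1 direction numbered 20 at day 12, 11 at day 40 and 9 between the exposure times, against at most 5, 4 and 2 in 1000 random orders. The smallest excess over the highest random order was 7 runs, which shows that neighbours changed together and not why. Strand and operon structure were not tested, so shared control of neighbouring loci was left open.

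The probes whose name begins with RNA_, 47 in all, were brighter on the first than on the second array of each group, by medians of 1.93, 2.98 and 1.89. The other probes differed by 0.0941, 0.017 and -0.0394. The unexposed group showed 1.93 too, so exposure to TiO2 is not needed for the difference. That value is part of the pattern and is no separate test of exposure. A handling difference shared by arrays of 1 number was left open, since the smallest of the 3 medians (1.89) only restates the pattern. What the probes measure is not given in the sources used here, and 0 and 1 of them were called by limma at day 12 and day 40.

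The third array of day 40 stood apart from the other day 40 arrays. Weak signal that acts most on dim genes was argued against, because the median distance was 0.578 in the dimmest and 0.56 in the brightest genes, a ratio of 1.03. A day 0 or day 12 sample under the wrong label was also argued against, because its mean correlation was higher with the other day 40 arrays (0.914) than with day 0 (0.872) or day 12 (0.885), by at least 0.0295. The spots of a gene spread more on this array, with an SD of 0.121 against 0.0395 to 0.0438 on the others, and a poor hybridisation of the whole array was not tested. A difference of its slide or scan cannot be told apart from a difference of the sample, since by scan date it was the only array of slide 2. No biological explanation was tested for it.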
